A study of Homo sapiens with 24 samples.

How the data were processed

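The series holds 24 poly-A RNA libraries of PMA-differentiated THP-1 cells in 4 groups of 6. Per the labels' protocols, cells were differentiated with 100 nM PMA for 24 h, treated with medium or 5 µM DCVC for 24 h, and given LPS at 100 ng/mL for 4 h after a change of medium, and RNA was extracted with a column kit and libraries were made by poly-A selection. Per the labels' protocols 1 and 10 µM DCVC were also used in the study, and no library of these doses was analysed here. The tools FastQC 0.11.5, MultiQC 0.9, STAR, featureCounts 1.6.1, R 3.6.0 and DESeq2 1.24.0 and the build hg38 are listed, without roles or order, per the submitters' processing notes. The STAR version, the annotation, the strand setting and the handling of reads with more than 1 hit are not given in the sources used here.

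The deposited table holds a signal per gene and library, namely read counts divided by a factor per library, so its values are normalized counts and not raw counts. That the authors divided whole reads by size factors was read from the values: within a library 100% of the values above 0 were whole multiples of the value of 1 read, within a tolerance of 0.1 read. The recovered reads in named genes ran from 18478618 to 30107819 per library. The factors differ between libraries, and the normalized totals differ between groups, at 21135356 ± 563705 (mean ± SD, n = 6) in Control, 17774466 ± 305501 in DCVC, 29427331 ± 839114 in LPS and 21831254 ± 235113 in DCVC_LPS. A scaling to equal totals therefore moves every gene relative to the deposited scale, and for the gene lists given in the text both are printed where the share of rises among the calls moved by over 10 percentage points, the calls or the median moved by over 1.5 times, or the median changed sign, which holds for 112 of 140 list tests. The 10 genes with most reads held 11.01 ± 1.03% of reads in Control, 9.41 ± 0.31% in DCVC, 11.39 ± 0.69% in LPS and 10.63 ± 0.21% in DCVC_LPS, and mitochondrial genes held 1.66%, 1.70%, 1.92% and 1.92% on average.

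Of 58381 entries, 19595 (33.56%) carry no gene name and about 1.01% of the values, and these stayed out of all comparisons. For 51 symbols on 2 entries the values were summed, which left 38735 named genes. The 13900 genes with a mean of at least 10 over the 24 libraries were tested. The unit called for a test of normalized values, the branch of the design fixed before the data were examined for that case. Values were tested as log2(value + 1), in which the pseudocount of 1 makes changes of low genes smaller than they are, with limma 3.58.1 in R 4.3.3 (empirical Bayes with a trend). All 24 libraries entered 1 fit with a mean per group and 20 residual degrees of freedom, so that the 4 groups share 1 estimate of the spread per gene. The comparisons were LPS minus Control, DCVC minus Control, DCVC_LPS minus LPS, DCVC_LPS minus DCVC, and the interaction, which is the difference between the LPS changes with and without DCVC. Genes with a Benjamini-Hochberg adjusted p under 0.05 are called raised or lowered.

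The slope of the LPS response with DCVC on that without it was fitted by total least squares through the origin over genes chosen on the mean of both LPS changes (adjusted p under 0.05 and at least 2-fold), a choice that does not favour either side, with an interval from leaving out each letter. The overlap of genes raised by LPS and lower in DCVC_LPS was set beside the overlap of independent lists, beside 20 simulations of unchanged groups sharing the LPS libraries, and beside splits of the LPS libraries. In total 28 gene lists with 609 genes, 536 of them tested, were fixed before the data were examined, as were the design, the comparisons, the rule for named genes and most alternatives. The lists were tested with camera at a preset correlation of 0.01, and again with an estimated correlation and with fry, and list p-values are adjusted over the lists of a comparison.

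Genes were named by a rule. For the first 3 comparisons it takes the 10 largest rises and 10 largest falls with adjusted p under 0.05, a mean of at least 50 and no overlap between the 6 values of both groups. For DCVC_LPS minus DCVC and the interaction it takes the 5 largest each way, without the condition on overlap for the interaction. From each list it adds up to 3 members that rose and 3 that fell with the smallest adjusted p, and always TNF, IL1B, IL6, CXCL8, CCL2, CCL3, IL10, IL1RN, PTGS2, NFKBIA, CXCL10, HMOX1, NQO1, TRIB3, KYAT1 and KYAT3. XIST and Y-linked genes are never named. Genes with near-identical copies, overlapping genes and antisense genes are named as uncertain. Not every gene the rule takes is described. Gene positions come from GENCODE 29 on GRCh38, in which 13526 of the 13900 tested symbols were found.

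The letters A to F are replicate names from the sample titles, and the labels do not say what they mark. Whether they pair samples was checked on the deviations of each library from its group mean. The 36 correlations between libraries of the same letter in different groups ran from 0.13 to 0.54, all above 0.1. The best match of a library in another group had the same letter in 27 of 36 cases, and the same letter or its partner in A/B, C/D or E/F in 36 of 36. Control library D, for example, had a correlation of 0.28 with DCVC library D and 0.33 with DCVC library C. The data thus pair the samples by the letter pairs, which alone could give such same-letter correlations, and less clearly by single letters. This pairing comes from the data and not from the labels. Within a group, libraries of such a letter pair differed by a chi-square per degree of freedom of 3.13 to 22.03 over genes with at least 20 reads, and others by 16.07 to 120.11, so no 2 libraries differed by sampling noise alone. Values within each letter pair are therefore given beside the pooled ones, but the fit has no term for the pairs and its p-values do not account for them.

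The steps were tested on simulated data of 13900 genes in which 200 genes changed at each of 1.5-, 2- and 4-fold together. This is a smaller part than was called in the data. At 2-fold, 86.5% of changed genes were recovered for LPS minus Control, 87.0% for DCVC minus Control, 88.0% for DCVC_LPS minus LPS, 87.5% for DCVC_LPS minus DCVC and 79.5% for the interaction. At 1.5-fold the shares were 61.5%, 66.5%, 63.5%, 67.5% and 48.5%, and at 4-fold 98.5%, 99.0%, 99.5%, 99.0% and 94.0%. A true slope of 0.6 was returned as 0.600, and 0 of 20 unchanged lists were called. Genes were simulated independently, without letter pairs and, for the slope, without an effect of DCVC alone. These checks therefore do not show how list calls or the slope behave with such structure. The alternatives fixed beforehand were other pseudocounts, filters, scalings (TMM factors and upper quartiles) and priors, fits of only the groups compared, the letter as a replicate block, edgeR 4.0.16 and DESeq2 1.42.0 on the recovered reads, and leaving out each letter and each library. Rescaling to equal totals, averaging the letter pairs (without a term for the pairs), edgeR without LPS library A and an exchanged split of the LPS libraries were added after seeing the data.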

Results

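RNA was measured in THP-1 cells, an established human monocytic leukaemia line, that had been turned into macrophage-like cells with the phorbol ester PMA. The 24 libraries fell into 4 groups of 6, each group holding the replicate letters A to F. Control cells received medium only. DCVC cells received 5 µM S-(1,2-dichlorovinyl)-L-cysteine, a cysteine conjugate formed in the metabolism of the solvent trichloroethylene, for 24 h. LPS cells received 100 ng/mL lipopolysaccharide, the outer-membrane component of gram-negative bacteria sensed by TLR4, for 4 h. DCVC_LPS cells received DCVC for 24 h and, after a change of medium, LPS for 4 h. The title of the series names the question: whether DCVC inhibits the inflammatory transcription induced by LPS. The reads per library in named genes ran from 19675823 to 27986524 in Control, 18478618 to 22015664 in DCVC, 19985317 to 30107819 in LPS and 20352552 to 26232127 in DCVC_LPS. Levels below are mean normalized counts ± SD (n = 6), and changes are log2 changes ± SE on log2(value + 1), with the limma adjusted p. The labels do not say that the 6 libraries of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical. Libraries whose letters form the pairs A/B, C/D and E/F resembled each other, and counts within each pair stand beside the pooled ones. Rises, falls and medians of lists with each library rescaled to the same total, an alternative chosen after seeing the data, are given as those under equal totals where they part from the deposited scale. Positions are GRCh38 gene bounds in GENCODE 29.

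In cells without DCVC, LPS raised cytokine, chemokine and interferon-stimulated genes. TNF (chromosome 6, 31575567 to 31578336, plus strand), a central inflammatory cytokine, rose from 286 ± 175 to 85844 ± 31751 normalized counts (log2 change 8.38 ± 0.35, adjusted p = 8.03e-17). IL1B (chromosome 2, 112829751 to 112836903, minus strand), which encodes the interleukin-1 beta precursor, rose from 17207 ± 5900 to 519241 ± 88586 (log2 change 5.01 ± 0.27, adjusted p = 9.15e-15). IL6 (chromosome 7, 22725884 to 22732002, plus strand), an acute-phase cytokine gene, had 2 reads over the 6 Control libraries and 11896 over the 6 LPS libraries, a ratio of 8217 (95% counting interval 2274 to 67856). IDO1 (chromosome 8, 39902275 to 39928444, plus strand), a tryptophan-degrading enzyme, had 0 reads in Control and was at least 17045-fold higher with LPS, against a floor of 3 reads over the group. CXCL10 (chromosome 4, 76021117 to 76023497, minus strand), an interferon-induced chemokine, rose from 4.31 ± 3.7 to 6304 ± 2311 (log2 change 10.45 ± 0.51, adjusted p = 1.62e-15). These intervals and floors cover counting error only.

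Further large rises were LAMP3 (log2 change 12.40 ± 0.38), a marker of dendritic cell maturation, ACOD1 (10.86 ± 0.26), which makes itaconate, the chemokine receptor CCR7 (10.57 ± 0.38) and the costimulatory ligand CD80 (9.88 ± 0.33). CCL4L2 (13.04 ± 0.50), CCL4 (11.28 ± 0.58) and CCL3L3 (10.59 ± 0.46) also rose, but they belong to chemokine families with near-identical copies between which reads can be split, so their values are uncertain. All 18 of 18 measured genes rose, with 18 adjusted over the list alone, in each of the lists of NF-kB pathway genes, cytokines and chemokines. Their median log2 changes were 4.83, 6.78 and 8.12, with camera adjusted p = 7.05e-12, 1.04e-08 and 4.47e-09. The NF-kB call had adjusted p = 0.138 with an estimated correlation, the cytokine call adjusted p = 0.0264 with an estimated correlation and the chemokine call adjusted p = 0.138 with an estimated correlation. TNFAIP2, a TNF-induced gene, rose by 7.40 ± 0.10, IL23A, a subunit of interleukin-23, by 9.17 ± 0.29 and CCL5, a T cell attractant, by 5.25 ± 0.17. Of the interferon and interferon-stimulated genes, 34 of 34 rose and 0 fell, also when adjusted over the list alone, with a median log2 change of 4.54 and camera adjusted p = 5.36e-14 (adjusted p = 0.305 with an estimated correlation). GBP5 and GBP2, interferon-induced GTPases, rose by 5.28 ± 0.18 and 5.64 ± 0.23, and the RNA sensor IFIH1 by 4.11 ± 0.17.

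Of the anti-inflammatory and feedback regulators, 13 of 15 rose and 2 fell, also when adjusted over the list alone, with a median log2 change of 2.90 and camera adjusted p = 0.000192 (adjusted p = 0.138 with an estimated correlation). SOCS3, an inhibitor of cytokine receptor signalling, rose from 16.4 ± 6.65 to 10144 ± 1540 and the interleukin-10 receptor subunit IL10RA from 1477 ± 109 to 16729 ± 3235. IL10 had 0 reads in Control and was at least 139-fold higher with LPS. Of the MHC class I presentation genes, 14 of 17 rose and 2 fell, also when adjusted over the list alone, with a median log2 change of 0.96 and camera adjusted p = 0.000759 (adjusted p = 0.433 with an estimated correlation). Equal totals gave 11 and 3 at a median of 0.48. The peptide transporter TAP1 rose from 2674 ± 323 to 21606 ± 4295 normalized counts. Of the immediate early genes, 13 of 19 rose and 4 fell, also when adjusted over the list alone, with a median log2 change of 2.36 and camera adjusted p = 0.0133 (adjusted p = 0.236 with an estimated correlation). NR4A3, a nuclear receptor, rose by 9.32 ± 0.32, whereas FOS, an AP-1 subunit, had a log2 change of -2.64 ± 0.14. All 13 of 13 mitochondrially encoded transcripts rose, also 13 adjusted over the list alone (median log2 change 0.81, camera adjusted p = 0.000857, adjusted p = 0.606 with an estimated correlation). Under equal totals, chosen after seeing the data, the median was 0.33 and 12 rose, as the mitochondrial share of reads was 1.66% in Control and 1.92% in LPS.

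Genes that fell with LPS included RGS4, a regulator of G-protein signalling (from 255 ± 79.4 to 2.86 ± 2.22 normalized counts, log2 change -6.24 ± 0.39), SIT1, a signalling adaptor (log2 change -6.19 ± 0.34), the scaffold kinase PEAK3 (-6.12 ± 0.34), the homeobox gene DLX3 (-6.09 ± 0.53) and the microtubule-associated MTUS1 (-5.37 ± 0.18). CD14 (chromosome 5, 140631728 to 140633701, minus strand), the LPS co-receptor, fell from 2520 ± 1026 to 176 ± 62 (log2 change -3.82 ± 0.28, adjusted p = 3.6e-12). MERTK, a receptor for apoptotic cells, and CEBPA, a myeloid transcription factor, had log2 changes of -4.40 ± 0.25 and -3.47 ± 0.15. HMOX1 (chromosome 22, 35380361 to 35394214, plus strand), which degrades haem, fell from 5718 ± 1077 to 978 ± 385 (log2 change -2.63 ± 0.22, adjusted p = 5.04e-11).

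In all, 5253 of 13900 tested genes rose and 5639 fell with LPS in the limma test at an adjusted p of 0.05, of which 2301 and 2778 changed at least 2-fold. For every gene named above as raised or lowered by LPS, 6 of 6 LPS libraries lay beyond all 6 Control libraries. Within the letter pairs the counts were 5091 up and 5236 down (A/B), 5182 up and 5579 down (C/D), 4577 up and 4776 down (E/F). Rescaling every library to the same total, an alternative chosen after seeing the data, shifted the median log2 change of all genes by -0.47 and gave 3119 genes up and 8275 down.

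DCVC alone raised NRF2 oxidative stress targets. SLC7A11 (chromosome 4, 138164097 to 138242349, minus strand), the cystine transporter that supplies glutathione synthesis, rose from 312 ± 233 to 4548 ± 954 normalized counts (log2 change 4.18 ± 0.31, adjusted p = 5.18e-11). GCLM (chromosome 1, 93885205 to 93909456, minus strand), a subunit of the enzyme that starts glutathione synthesis, rose from 442 ± 48.2 to 4000 ± 116 (log2 change 3.18 ± 0.10, adjusted p = 1.83e-17). HMOX1 rose from 5718 ± 1077 to 20053 ± 2576 (log2 change 1.82 ± 0.22, adjusted p = 1.45e-07). IGFBP5 (chromosome 2, 216672105 to 216695525, minus strand), which binds insulin-like growth factors, fell from 140.1 ± 92.2 to 1.04 ± 1.82 (log2 change -6.25 ± 0.50, adjusted p = 2.22e-10). TLR8, an endosomal sensor of RNA, fell from 137 ± 43.9 to 2.23 ± 0.456 (log2 change -5.38 ± 0.28, adjusted p = 1e-13).

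Of the NRF2 oxidative stress targets, 21 of 24 rose and 0 fell, also when adjusted over the list alone, with a median log2 change of 1.62 and camera adjusted p = 1.37e-15, a call kept with an estimated correlation (adjusted p = 0.0281 with an estimated correlation). TXNRD1, which reduces thioredoxin, rose by 2.45 ± 0.09 on the log2 scale, the quinone reductase NQO1 by 1.61 ± 0.13 and PIR by 2.60 ± 0.08. Other large rises were SGPP2 (4.81 ± 0.28), which removes phosphate from sphingosine 1-phosphate, ZNF365 (4.21 ± 0.36) and TNIP3 (3.33 ± 0.28), an inhibitor of NF-kB signalling. TREML3P (5.49 ± 0.37) and NMRAL2P (5.42 ± 0.23) are pseudogenes and TRIM16L (3.30 ± 0.26) resembles TRIM16, so their values are uncertain. KYAT1, a beta-lyase that cleaves cysteine conjugates, rose from 27.1 ± 3.41 to 43.9 ± 3.4 normalized counts (log2 change 0.68 ± 0.20, adjusted p = 0.00464). It does not stand for its list of cysteine conjugate and glutathione handling genes, of which 11 of 27 rose and 11 fell.

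Among the largest falls were ADRA2B, an adrenergic receptor (log2 change -6.23 ± 0.53), CEMIP, which degrades hyaluronan (-5.92 ± 0.33), the intermediate filament gene NES (-5.76 ± 0.48), the sphingosine 1-phosphate receptor S1PR1 (-5.74 ± 0.52), the collagen COL10A1 (-5.70 ± 0.89) and the caveolae protein CAV1 (-5.10 ± 0.25). CD14 fell from 2520 ± 1026 to 289 ± 109 normalized counts (log2 change -3.11 ± 0.28, adjusted p = 1.08e-09). Of the TLR4 receptor complex and adaptors, 4 of 26 rose and 16 fell (adjusted over the list alone, 4 and 17), with a median log2 change of -0.41 and camera adjusted p = 0.0312 (adjusted p = 0.178 with an estimated correlation). Equal totals gave 8 and 10 at a median of -0.16. TAB2, an adaptor of the kinase TAK1, had a log2 change of -1.50 ± 0.07 and TLR7 of -3.76 ± 0.29. Of the inflammasome and pyroptosis genes, 0 of 15 rose and 10 fell, also when adjusted over the list alone, with a median log2 change of -0.72 and camera adjusted p = 0.0242 (adjusted p = 0.243 with an estimated correlation). Equal totals gave 0 and 7 at a median of -0.47. The sensors NLRP3 and AIM2 had log2 changes of -1.63 ± 0.10 and -2.43 ± 0.34. Of the scavenger receptors, 1 of 16 rose and 11 fell, also when adjusted over the list alone, with a median log2 change of -0.98 and camera adjusted p = 0.0126 (adjusted p = 0.231 with an estimated correlation). OLR1 and CD36, receptors for oxidized lipoproteins, changed by -3.81 ± 0.34 and -1.85 ± 0.15. Of the ATF4 stress response genes, 3 of 29 rose and 18 fell, also when adjusted over the list alone, with a median log2 change of -0.53 and camera adjusted p = 0.0167 (adjusted p = 0.253 with an estimated correlation). Equal totals gave 7 and 15 at a median of -0.28. The amino acid transporter SLC7A5 and the hormone STC2 had log2 changes of -1.71 ± 0.11 and -3.74 ± 0.32.

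Inflammatory genes went both ways at baseline. TNF fell from 286 ± 175 to 83.3 ± 35.3 normalized counts (log2 change -1.61 ± 0.35, adjusted p = 0.00035) and IL1B from 17207 ± 5900 to 5425 ± 1812 (log2 change -1.65 ± 0.27, adjusted p = 1.12e-05), while the chemokine CCL22 rose from 25.3 ± 5.78 to 100 ± 6.33 (log2 change 1.97 ± 0.18, adjusted p = 2.04e-09). CXCL8, a neutrophil attractant, stood at 6501 ± 4273 and 12050 ± 6417 (log2 change 1.15 ± 0.50, adjusted p = 0.0499). Its adjusted p ran from 0.00457 to 0.213 over the alternatives, above 0.05 without any of DCVC A, DCVC B, DCVC C, DCVC D, Control E, Control F or the letters A, B, C, D, E, F. Of the NF-kB genes, 2 of 18 rose and 13 fell (adjusted over the list alone, 3 and 14), with a median log2 change of -0.56 and camera adjusted p = 0.0741. Equal totals gave 3 and 9 at a median of -0.31. Of the cytokines, 2 of 18 rose and 6 fell, also when adjusted over the list alone, with a median log2 change of -0.19 and camera adjusted p = 0.691. Equal totals gave 3 and 5 at a median of -0.14. Of the interferon-stimulated genes, 4 of 34 rose and 9 fell (adjusted over the list alone, 3 and 9), with a median log2 change of -0.21 and camera adjusted p = 0.666. Equal totals gave 9 and 6 at a median of -0.02. The cytokine median was -0.08 with genes absent from a group at their bound. In all, 3820 genes rose and 4478 fell with DCVC, 855 and 1487 of them at least 2-fold. For the genes named above as raised or lowered by DCVC, 6 of 6 DCVC libraries lay beyond all 6 Control libraries, except TNF (4 of 6), CXCL8 (4 of 6) and IL1B (3 of 6). These counts compare libraries across letters. Between libraries of the same letter, TNF and IL1B were lower in DCVC than in Control for every letter. Within the letter pairs the counts were 3496 up and 4383 down (A/B), 3924 up and 4734 down (C/D), 2294 up and 3301 down (E/F). Rescaling every library to the same total, an alternative chosen after seeing the data, shifted the median log2 change of all genes by 0.25 and gave 6414 genes up and 2791 down.

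DCVC_LPS was set against LPS to ask whether pretreatment with DCVC changed expression in LPS-stimulated cells. TNF was 7278 ± 848 normalized counts in DCVC_LPS against 85844 ± 31751 in LPS, a log2 change of -3.46 ± 0.35, adjusted p = 3.52e-09. IL6 fell from 2504 ± 571 to 40.7 ± 21.8 (log2 change -5.99 ± 0.26, adjusted p = 1.27e-15), IL1B from 519241 ± 88586 to 165675 ± 16289 (log2 change -1.63 ± 0.27, adjusted p = 6.59e-06) and CXCL10 from 6304 ± 2311 to 226 ± 213 (log2 change -5.11 ± 0.51, adjusted p = 2.79e-09). CCL2 (chromosome 17, 34255218 to 34257203, plus strand), a monocyte attractant, fell from 1649 ± 403 to 19.8 ± 12 (log2 change -6.50 ± 0.38, adjusted p = 2.39e-13), close to its Control level of 21.9 ± 13.8. HMOX1 rose from 978 ± 385 to 25734 ± 7283 (log2 change 4.77 ± 0.22, adjusted p = 3.3e-15). Levels per library of these genes, GCLM and CD14 are plotted by group.

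**Figure D1:**
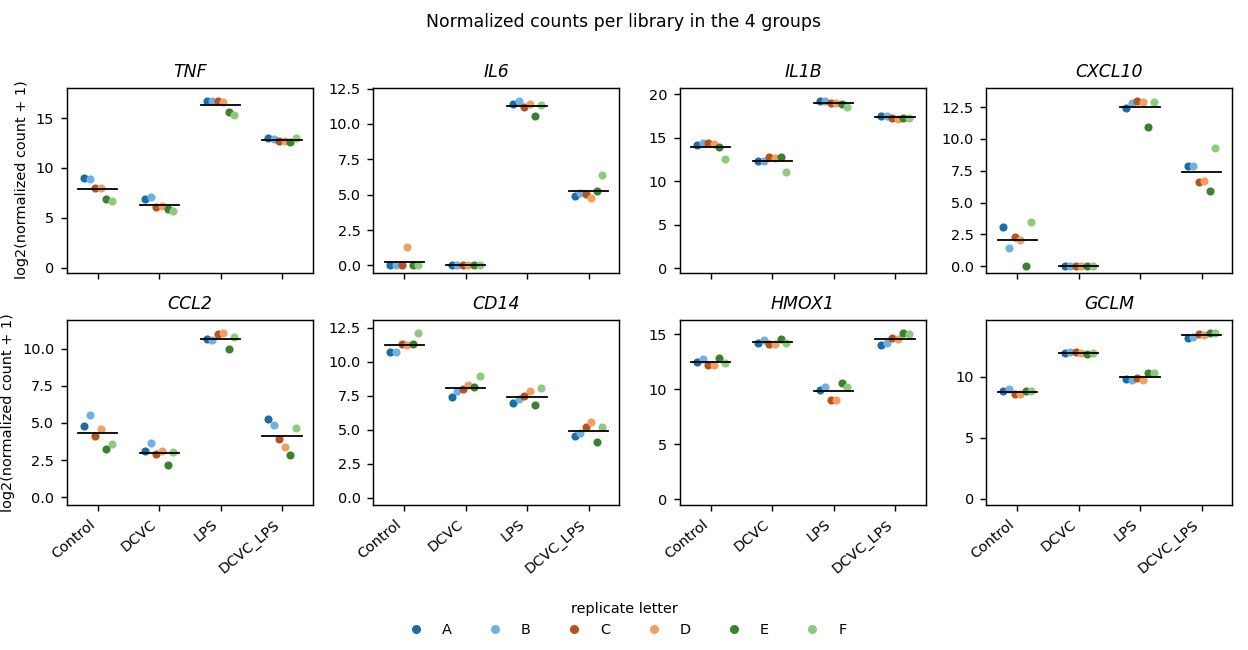
Normalized counts of 8 genes on the scale log2(value + 1) (vertical axis) in the 6 libraries of each of the 4 groups (horizontal axis), with points coloured by replicate letter and bars at the group mean. TNF, IL6, IL1B, CXCL10 and CCL2 are lower in DCVC_LPS than in LPS (for TNF by a log2 change of -3.46), and HMOX1 and GCLM are higher (for HMOX1 by 4.77).

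The adhesion molecule VCAM1 (chromosome 1, 100719742 to 100739045, plus strand) fell from 849.9 ± 218 to 2.51 ± 2.62 normalized counts (log2 change -8.12 ± 0.49, adjusted p = 4.45e-13). Further large falls were the interferon-gamma-induced chemokine CXCL9 (log2 change -7.51 ± 0.42), S1PR1 (-7.44 ± 0.52), the matricellular gene CCN2 (-7.23 ± 0.43), the granzyme B inhibitor SERPINB9 (-7.11 ± 0.42), IDO1 (-6.21 ± 0.38), CXCL11 (-6.03 ± 0.53) and CCL1 (-6.02 ± 0.47). Of the cytokines, 0 of 18 rose and 17 fell, also when adjusted over the list alone, with a median log2 change of -2.83 and camera adjusted p = 3.72e-05 (adjusted p = 0.109 with an estimated correlation). CSF2, a growth factor for macrophages and granulocytes, and IL12B, a subunit of interleukin-12, had log2 changes of -4.33 ± 0.20 and -5.98 ± 0.44. Of the chemokines, 0 of 18 rose and 17 fell, also when adjusted over the list alone, with a median log2 change of -1.83 and camera adjusted p = 0.000527 (adjusted p = 0.36 with an estimated correlation). CXCL8 stood at 586655 ± 116473 in LPS and 260193 ± 28581 in DCVC_LPS (log2 change -1.15 ± 0.50, adjusted p = 0.0406). Its adjusted p ran from 2.75e-06 to 0.184 over the alternatives, above 0.05 without any of DCVC_LPS A, LPS A, DCVC_LPS B, LPS B, LPS C, DCVC_LPS D, LPS D, DCVC_LPS E, DCVC_LPS F or the letters A, B, C, D. The SE of CXCL8 is drawn from all 4 groups, and relative to the mean its SD was larger in Control and DCVC than here. All 6 of 6 DCVC_LPS libraries lay below the LPS libraries. CCL3, whose near-identical copies make it uncertain, had a log2 change of -1.78 ± 0.34.

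Of the interferon and interferon-stimulated genes, 0 of 34 rose and 34 fell, also when adjusted over the list alone, with a median log2 change of -2.93 and camera adjusted p = 9.16e-12 (adjusted p = 0.328 with an estimated correlation). HERC5 (chromosome 4, 88457117 to 88506163, plus strand), a ligase of the interferon-induced ubiquitin-like system, fell from 3603 ± 869 to 136 ± 104 normalized counts (log2 change -4.90 ± 0.27, adjusted p = 9.31e-14), the GTPase GBP4 from 7589 ± 1805 to 407 ± 219 (log2 change -4.30 ± 0.22, adjusted p = 1.97e-14) and STAT2, which carries type I interferon signals, from 6048 ± 1119 to 1151 ± 549 (log2 change -2.47 ± 0.16, adjusted p = 2.01e-12). Of the NF-kB genes, 0 of 18 rose and 17 fell, also when adjusted over the list alone, with a median log2 change of -0.92 and camera adjusted p = 0.000108 (adjusted p = 0.402 with an estimated correlation). Equal totals gave 0 and 11 at a median of -0.49. The NF-kB subunit genes NFKB1 and REL changed by -1.07 ± 0.08 and -1.61 ± 0.11. Of the MHC class I presentation genes, 0 of 17 rose and 15 fell, also when adjusted over the list alone, with a median log2 change of -0.73 and camera adjusted p = 8.41e-05 (adjusted p = 0.328 with an estimated correlation). Equal totals gave 1 and 10 at a median of -0.30. Of the feedback regulators, 1 of 15 rose and 10 fell, also when adjusted over the list alone, with a median log2 change of -1.22 and camera adjusted p = 0.0137 (adjusted p = 0.328 with an estimated correlation). Equal totals gave 2 and 10 at a median of -0.79. The interleukin-1 receptor antagonist IL1RN had a log2 change of -1.61 ± 0.16. IL10 was 63 ± 16.7 in LPS and 0.69 ± 1.29 in DCVC_LPS (log2 change -5.44 ± 0.36), and PTGS2, the inducible cyclooxygenase, fell from 10089 ± 5871 to 1424 ± 279 (log2 change -2.63 ± 0.28, adjusted p = 9.25e-09). Of the inflammasome genes, 1 of 15 rose and 10 fell, also when adjusted over the list alone, with a median log2 change of -1.28 and camera adjusted p = 0.0333 (adjusted p = 0.328 with an estimated correlation). Equal totals gave 3 and 9 at a median of -0.86. The protease CASP1 changed by -2.09 ± 0.16 and NLRP3 by -2.07 ± 0.10. MYD88, the adaptor of most TLRs, had a log2 change of -2.40 ± 0.13 and CD14 of -2.50 ± 0.28. Both belong to the TLR4 receptor list, of which 8 of 26 genes rose and 13 fell at a median log2 change of -0.18. Under equal totals 13 rose and 10 fell at a median of 0.25.

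Of the NRF2 targets, 23 of 24 rose and 0 fell, also when adjusted over the list alone, with a median log2 change of 1.89 and camera adjusted p = 5.55e-13 (adjusted p = 0.0618 with an estimated correlation). GCLM rose from 1017 ± 199 to 11138 ± 1206 normalized counts (log2 change 3.47 ± 0.10, adjusted p = 1.36e-18), OSGIN1, an oxidative stress response gene, from 209 ± 37 to 4677 ± 597 (log2 change 4.49 ± 0.15, adjusted p = 1.34e-17), and the glutathione reductase GSR from 2150 ± 148 to 14296 ± 1264 (log2 change 2.73 ± 0.08, adjusted p = 4.07e-18). ZNF365 (5.28 ± 0.36), SH3TC2 (4.48 ± 0.44) and the diacylglycerol kinase DGKG (4.07 ± 0.15) were among the largest log2 rises. Of the cholesterol biosynthesis genes, 18 of 23 rose and 3 fell, also when adjusted over the list alone, with a median log2 change of 0.97 and camera adjusted p = 0.00801 (adjusted p = 0.708 with an estimated correlation). This call did not hold after rescaling to equal totals (adjusted p = 0.101, 3.03e-05 to 0.708 over the alternatives). FDFT1, the squalene synthase, rose from 1761 ± 322 to 6751 ± 2400 and the isomerase IDI1 from 432 ± 64.9 to 1719 ± 683. KYAT1 rose from 13.7 ± 6.41 to 31.7 ± 6.74 (log2 change 1.23 ± 0.20, adjusted p = 5.09e-06), while 10 of 27 genes of its list rose and 9 fell.

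In all, 4633 genes were higher and 5478 lower in DCVC_LPS than in LPS, 1656 and 2158 of them by at least 2-fold. For the genes named above as higher or lower in DCVC_LPS, 6 of 6 DCVC_LPS libraries lay beyond all 6 LPS libraries, except KYAT1 (4 of 6). Within the letter pairs the counts were 4340 up and 5490 down (A/B), 4786 up and 5525 down (C/D), 3442 up and 4567 down (E/F). Rescaling every library to the same total, an alternative chosen after seeing the data, shifted the median log2 change of all genes by 0.43 and gave 7578 genes up and 3051 down. Across genes, which are not independent replicates, the DCVC effect without LPS and that with LPS had Pearson r = 0.69 and Spearman rho = 0.66. These 2 comparisons share no library, and 2698 genes were up and 3218 down in both, where independent lists would share 1273 and 1765.

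**Figure D2:**
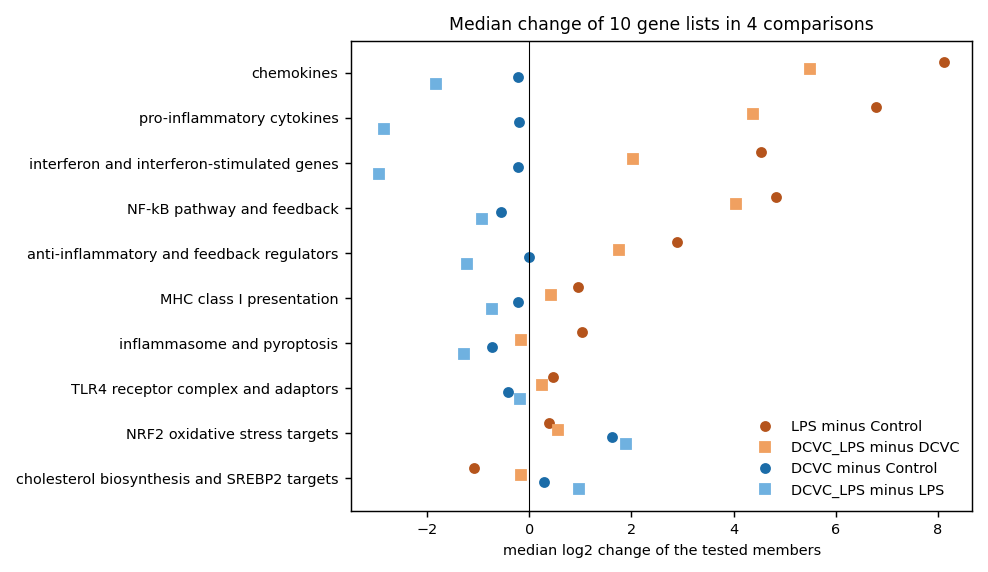
Median log2 change (horizontal axis) of the tested members of 10 gene lists (vertical axis) in 4 comparisons, orange for the effect of LPS and blue for the effect of DCVC, circles without and squares with the other treatment. The interferon list has a median of 4.54 for LPS without DCVC and 2.03 with DCVC, and the NRF2 list has medians of 1.62 and 1.89 for DCVC without and with LPS.

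Cells that had received DCVC still responded to LPS. From DCVC to DCVC_LPS, TNF rose from 83.3 ± 35.3 to 7278 ± 848 normalized counts (log2 change 6.52 ± 0.35, adjusted p = 3.89e-14), IL1B from 5425 ± 1812 to 165675 ± 16289 (log2 change 5.02 ± 0.27, adjusted p = 3.38e-14) and the chemokine CCL20 from 64.5 ± 30.4 to 26100 ± 7348 (log2 change 8.73 ± 0.31, adjusted p = 1.12e-17). CXCL10 and IL6, with 0 reads in DCVC, were at least 515-fold higher and at least 92-fold higher in DCVC_LPS. IL10 was near its floor, at 0.579 ± 0.703 and 0.69 ± 1.29 normalized counts (log2 change -0.04 ± 0.36, adjusted p = 0.927). Falls included PDK4, which inhibits pyruvate dehydrogenase (log2 change -4.98 ± 0.39), MTUS1 (-4.53 ± 0.18) and the repressor SNAI3 (-4.53 ± 0.31). ADORA2A-AS1, an antisense gene, had 1 read over the DCVC libraries and 2625 over the DCVC_LPS libraries, but its reads cannot be told from those of overlapping genes without knowing the strand setting.

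Of the NF-kB genes, 18 of 18 rose and 0 fell, also when adjusted over the list alone, with a median log2 change of 4.05 and camera adjusted p = 2.82e-18 (adjusted p = 0.0644 with an estimated correlation). Of the cytokines, 16 of 18 rose and 0 fell, also when adjusted over the list alone, with a median log2 change of 4.38 and camera adjusted p = 8.03e-09 (adjusted p = 0.0248 with an estimated correlation). Of the chemokines, 17 of 18 rose and 0 fell, also when adjusted over the list alone, with a median log2 change of 5.49 and camera adjusted p = 1.12e-09 (adjusted p = 0.117 with an estimated correlation). Of the interferon-stimulated genes, 34 of 34 rose and 0 fell, also when adjusted over the list alone, with a median log2 change of 2.03 and camera adjusted p = 8.75e-11 (adjusted p = 0.429 with an estimated correlation). Their median was 2.02 with genes absent from a group at their bound. Of the NRF2 targets, 17 of 24 rose and 0 fell, also when adjusted over the list alone, with a median log2 change of 0.57 and camera adjusted p = 1.65e-05 (adjusted p = 0.212 with an estimated correlation). Equal totals gave 13 and 1 at a median of 0.28. TXNRD1 rose by 1.69 ± 0.09 and OSGIN1 by 2.05 ± 0.15. Of the feedback regulators, 11 of 15 rose and 3 fell, also when adjusted over the list alone, with a median log2 change of 1.75 and camera adjusted p = 0.00069 (adjusted p = 0.186 with an estimated correlation). Of the immediate early genes, 12 of 19 rose and 2 fell, also when adjusted over the list alone, with a median log2 change of 0.94 and camera adjusted p = 0.0155 (adjusted p = 0.212 with an estimated correlation). Equal totals gave 10 and 4 at a median of 0.67. SOCS3 and DUSP1, which damp cytokine and MAP kinase signals, rose by 6.62 ± 0.23 and 3.21 ± 0.17. All 13 of 13 mitochondrially encoded transcripts rose again, also 13 adjusted over the list alone (median log2 change 0.46, camera adjusted p = 0.00393, adjusted p = 0.661 with an estimated correlation). Under equal totals, chosen after seeing the data, the median was 0.16 and 1 rose, as the mitochondrial share of reads was 1.70% in DCVC and 1.92% in DCVC_LPS. Of the MHC class I presentation genes, 11 of 17 rose and 3 fell, also when adjusted over the list alone, with a median log2 change of 0.43 and camera adjusted p = 0.0438 (adjusted p = 0.661 with an estimated correlation). Equal totals gave 6 and 6 at a median of 0.14. The call did not hold after rescaling to equal totals (adjusted p = 0.0902, 8.08e-06 to 0.661 over the alternatives). In all, 4160 genes rose and 4475 fell, with 3808 up and 4065 down (A/B), 4195 up and 4231 down (C/D), 3398 up and 3496 down (E/F) within the letter pairs. For the genes named above as changed from DCVC to DCVC_LPS, 6 of 6 DCVC_LPS libraries lay beyond all 6 DCVC libraries. Rescaling every library to the same total, an alternative chosen after seeing the data, shifted the median log2 change of all genes by -0.29 and gave 2263 genes up and 7322 down.

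The LPS response itself was compared with and without DCVC by the interaction of both treatments. CCR7 (chromosome 17, 40553769 to 40565472, minus strand), which guides migration to lymph nodes, rose with LPS from 1.09 ± 1.53 to 2759 ± 1064 normalized counts without DCVC and from 12.3 ± 5.56 to 54.6 ± 27.6 with it (interaction log2 -8.54 ± 0.53, adjusted p = 2.02e-11). NR4A3 rose by 9.32 without and 1.71 with DCVC (interaction -7.61 ± 0.45, adjusted p = 1.03e-11), and HERC5 by 6.17 and 0.73 (interaction -5.44 ± 0.38, adjusted p = 1.11e-10). The TNF interaction was -1.85 ± 0.49, adjusted p = 0.00353, and adjusted p = 2.99e-05 with the replicate letter as a block. With letter pairs averaged it had adjusted p = 0.0722, the highest over the alternatives (2.99e-05 to 0.0722). That fit has 3 values per group and no term for the pairs, so differences between pairs stay in its spread. Within each letter the log2 rise of TNF was smaller with DCVC than without it. IL1B rose by 5.01 and 5.02, an interaction of 0.01 ± 0.38 that did not pass the test (adjusted p = 0.984), and its DCVC change was -1.65 without LPS and -1.63 with it. IL6, CSF2, CXCL9, IDO1 and IL12B, nearly absent without LPS, had interactions of -5.77, -4.17, -7.67, -6.54 and -6.10, which depend on the pseudocount and did not pass in edgeR on recovered reads (adjusted p from 0.0797 to 0.919). The CXCL10 interaction of -3.07 turned to 0.35 in edgeR. CCL2, IL1A and CCL22 had interactions of -5.20 ± 0.54, -4.67 ± 0.46 and -4.81 ± 0.26.

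Of the interferon and interferon-stimulated genes, 0 of 34 had a positive and 33 a negative interaction, also 0 and 33 adjusted over the list alone (median log2 -2.46, camera adjusted p = 5.11e-17, adjusted p = 0.409 with an estimated correlation). Positive and negative interactions numbered 0 and 14 of 18 cytokines (0 and 14 adjusted over the list alone, median -2.26, camera adjusted p = 2.15e-06, adjusted p = 0.0865 with an estimated correlation). Chemokines had 1 and 13 of 18 (1 and 14 adjusted over the list alone, median -2.10, camera adjusted p = 7.54e-05, adjusted p = 0.503 with an estimated correlation). NF-kB genes had 1 and 9 of 18 (1 and 9 adjusted over the list alone, median -0.60, camera adjusted p = 0.00942, adjusted p = 0.743 with an estimated correlation). NRF2 targets had 10 and 1 of 24 (10 and 1 adjusted over the list alone, median 0.29, camera adjusted p = 0.0306, adjusted p = 0.702 with an estimated correlation, equal totals 14 and 1 at a median of 0.47), a call lost with the replicate letter as a block (adjusted p = 0.0507) and with letter pairs averaged (adjusted p = 0.052, 0.0015 to 0.702 over the alternatives). The cytokine and chemokine lists hold genes nearly absent without LPS, such as IL6, CSF2, IL12B, CXCL9 and CXCL10. Their interactions depend on the pseudocount, which limits the counts, medians and tests of these lists. No list test was run on recovered reads. Positive interactions included HMOX1 (2.95 ± 0.31), GSR (1.23 ± 0.12), RGS4 (5.02 ± 0.55) and DGKG (3.31 ± 0.21). RGS4 was near its floor in LPS, and 0 of 6 DCVC_LPS libraries lay beyond the LPS libraries, so its value does not show a rise. In all, 3053 genes had a positive and 3297 a negative interaction, with 2692 up and 3234 down (A/B), 3640 up and 3495 down (C/D), 1281 up and 1578 down (E/F) within the letter pairs. With letter pairs averaged, an alternative chosen after seeing the data, 1679 and 2085 remained, and 59.26% of the 6350 calls were kept. That fit has no term for the pairs. Of the 6350 calls, 6306 (99.31%) had the same sign in all 3 letter pairs. The calls were chosen on these same libraries, which favours such agreement. Rescaling to equal totals shifted the median by 0.18 and gave 4601 and 2233, and TMM factors shifted it by 0.12 and gave 4045 and 2540.

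Over 3683 genes that LPS changed at least 2-fold on average, the LPS log2 change with DCVC had a slope of 0.647 on that without DCVC, with a jackknife 95% interval over letters of 0.616 to 0.677. Its jackknife SE was 0.0158 over letters and 0.0254 over the 3 letter pairs. The slope was 0.642, 0.603 and 0.686 in the letter pairs A/B, C/D and E/F. Of the 1642 raised genes 1391 rose less with DCVC, and of the 2041 lowered genes 1809 fell less. Of the 2301 genes that LPS raised at least 2-fold, 1872 were lower and 114 higher in DCVC_LPS than in LPS. Of the 2778 that it lowered at least 2-fold, 1574 were higher and 498 lower in DCVC_LPS. With genes chosen on LPS libraries A, C and E and compared with B, D and F, 1794 of 2292 raised genes were lower and 102 higher, and 1453 of 2722 lowered genes were higher and 420 lower. With these libraries exchanged, the counts were 1804 and 103 of 2333 and 1441 and 450 of 2763. Each part holds a library of every letter pair, so what the libraries of a pair share still enters both the choice and the comparison.

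**Figure D3:**
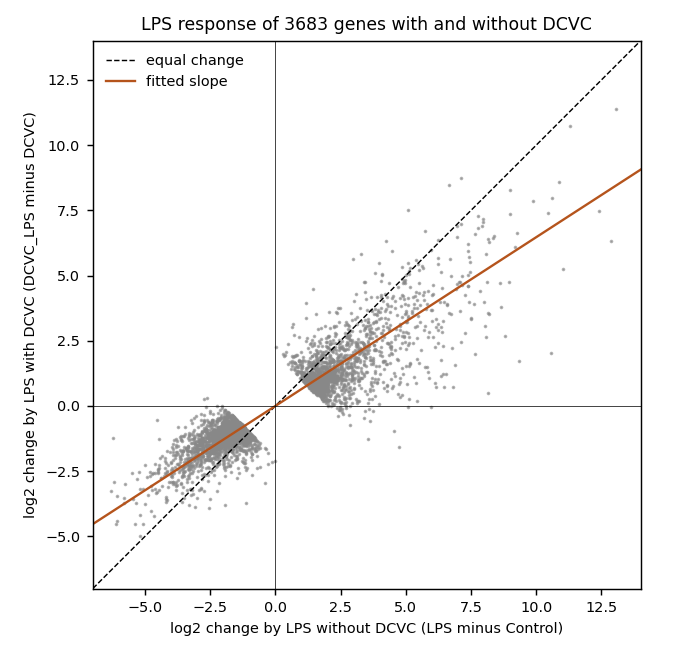
Log2 change by LPS without DCVC (horizontal axis) and with DCVC (vertical axis) for the 3683 genes used in the slope, 1 point per gene. The fitted line has a slope of 0.647 and the dashed line marks equal change.

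In all, 3457 genes were raised by LPS and lower in DCVC_LPS than in LPS, and 3117 were lowered by LPS and higher in DCVC_LPS, where independent lists would share 2070 and 1880. Because both comparisons use the LPS libraries, unchanged groups were simulated 20 times. Almost no gene is called in such groups, so their overlap of 0 is no measure for these counts, but they had r = -0.50 and a covariance of -0.020 across genes, against r = -0.52 and a covariance of -0.912 in the data. With the LPS libraries split between the comparisons the counts were 3106 and 2723 for 1 split and 3137 and 2713 with the parts exchanged. Both parts hold a library of each letter pair, so these splits do not remove what the libraries of a pair share. Rescaling to equal totals, chosen after seeing the data, gave 1667 and 5902.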

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

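The tests of the scaling and of the letter pairs against the smaller LPS response, and that of IFNB1, were chosen only after the result was seen. In 55 of 484 groups of 6 values, made of 116 genes named in the text and 5 features of the libraries, the most extreme library lay apart from the others by a large share of the group's range, given here for each gene, and chance alone does so in about 1 of 20 groups. LPS library E was the lowest of its group in 11 of them, with shares for ACOD1 (0.655), CCL5 (0.679), CXCL10 (0.747), CXCL11 (0.802), CXCL9 (0.752), GBP4 (0.732), HERC5 (0.808), IFIH1 (0.764), IL10 (0.687), NR4A3 (0.94) and SOCS3 (0.691). DCVC_LPS library F was the highest in 15, for CCL3 (0.824), CCL3L3 (0.749), CCL4 (0.667), CCL4L2 (0.851), CCL5 (0.634), GBP4 (0.663), GBP5 (0.813), HERC5 (0.703), IDO1 (0.674), IFIH1 (0.706), IL6 (0.701), LAMP3 (0.693), MYD88 (0.673), STAT2 (0.775) and WARS1 (0.7). DCVC_LPS library D was lowest for ADRA2B (0.728). LPS library F was highest for CASP1 (0.669), CD40 (0.786), LAMP3 (0.739) and TNIP3 (0.634). DCVC library E was lowest for CAV1 (0.662). LPS library B was lowest for CD68 (0.667). Control library F was lowest for FDFT1 (0.627), IL1B (0.767) and TNFAIP2 (0.922). DCVC_LPS library F was lowest for FOS (0.657). Control library F was highest for HERC5 (0.648), MCM7 (0.722) and TLR7 (0.678). LPS library F was lowest for IDI1 (0.755). DCVC library F was lowest for IL1B (0.698), PTGS2 (0.673) and TNFAIP2 (0.693). LPS library C was lowest for STC2 (0.66). DCVC_LPS library E was lowest for TNFAIP2 (0.694). DCVC_LPS library C was highest for TXNRD1 (0.784). The share was 1 for ADORA2A-AS1 in DCVC, CSF2 in Control, CXCL11 in DCVC, CXCL9 in DCVC, IDO1 in DCVC, IL12B in DCVC, IL12B in Control and IL6 in Control, where 1 library held all reads of the group. Leaving out LPS library E or DCVC_LPS library F kept each count of genes within 1.5 times its value.

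The LPS change differed between cells with and without DCVC, by the interaction test, in 3053 genes in the positive and 3297 in the negative direction, among them 83 genes named in the text. The log2 interaction was positive in RGS4 (5.02), ADRA2B (4.01), DGKG (3.31), SIT1 (3.29), HMOX1 (2.95), SH3TC2 (2.20), STC2 (1.85), ADORA2A-AS1 (1.82), OSGIN1 (1.63), MERTK (1.62), CCL20 (1.61), PEAK3 (1.61), FOS (1.57), OLR1 (1.45), CEMIP (1.33), GSR (1.23), IDI1 (1.04), FDFT1 (1.02), CEBPA (0.98), MTUS1 (0.84), CD36 (0.82), TAB2 (0.73), DNAJB1 (0.60), GLA (0.48) and PIR (0.39). The most negative values were those of CCR7 (-8.54), CXCL9 (-7.67), NR4A3 (-7.61), IDO1 (-6.54), IL12B (-6.10), IL10 (-5.99), IL6 (-5.77), CCL1 (-5.44), HERC5 (-5.44), VCAM1 (-5.32), CCL2 (-5.20), CCN2 (-5.17), LAMP3 (-4.91), CXCL11 (-4.87) and CCL22 (-4.81). Further negative values were found for IL1A (-4.67), CSF2 (-4.17), TNIP3 (-4.02), GBP4 (-3.71), SERPINB9 (-3.11), CXCL10 (-3.07), IL23A (-3.05), GBP5 (-2.86), TNFAIP2 (-2.80), SOCS3 (-2.66), CCL3L3 (-2.59), SGPP2 (-2.52), PTGS2 (-2.51), IFIH1 (-2.38) and CXCL8 (-2.30). Values closer to 0 were negative for ACOD1 (-2.28), STAT2 (-2.11), CD80 (-2.02), WARS1 (-1.94), CCL3 (-1.90), TNF (-1.85), MYD88 (-1.78), TAP1 (-1.71), CCL5 (-1.69), CASP1 (-1.67), IL10RA (-1.66), NMRAL2P (-1.60), SRGN (-1.41), GBP2 (-1.39) and CD40 (-1.35). The smallest negative values were those of NFKBIA (-0.98), TLR4 (-0.90), IL1RN (-0.85), MT-ND2 (-0.68), REL (-0.62), HSP90AB1 (-0.59), NFKB1 (-0.59), HLA-G (-0.57), CTSS (-0.48), KYAT3 (-0.44), NLRP3 (-0.44), UQCRFS1 (-0.29) and ATP5F1B (-0.18). Values of genes nearly absent without LPS, such as IL6, CSF2, CXCL9, CXCL10, IDO1 and IL12B, depend on the pseudocount. A positive value need not be a rise. RGS4 was near its floor in LPS, and 0 of 6 DCVC_LPS libraries lay beyond the LPS libraries. ADRA2B was among the largest falls with DCVC alone, and 0 of 6 DCVC_LPS libraries lay beyond the DCVC libraries. At least 1 alternative took the adjusted p over 0.05, at most to the value given, for CCL20 (0.0629), CCL3 (0.058), CD80 (0.0851), CSF2 (0.833), CTSS (0.081), CXCL10 (0.962), CXCL8 (0.114), CXCL9 (0.108), HLA-G (0.0984), IDO1 (0.218), IL12B (0.0816), IL1RN (0.0573), IL6 (0.919), KYAT3 (0.15), MT-ND2 (0.0613), NFKBIA (0.161), TNF (0.0722) and UQCRFS1 (0.26). Of 1174 entries without a gene name and a mean of at least 10, which no comparison uses, 305 were higher and 455 lower with LPS than in Control in a limma test of these entries alone.

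The slope of 0.647 of the LPS response with DCVC on that without it lies under 1. The scaling of the deposited values was argued against, since the slope was 0.655 with each library rescaled to the same total. Over 991 genes with a mean of at least 1000 the slope was 0.704 (jackknife SE 0.016), still under 1. That mean is over all 24 libraries, so genes high only with LPS, such as CXCL10, passed while near their floor without it. The test therefore cannot exclude compression of changes in genes with few reads, which remains open. A difference between the letter pairs was argued against by the highest slope of the 3 pairs, 0.686. A smaller LPS response of DCVC-treated macrophages may be biological, as a hypothesis found and tested on the same data, with a part of compression left open.

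Interferon-stimulated genes kept less of their LPS response with DCVC than NF-kB pathway genes, with a median share of 0.451 over 34 genes against 0.873 over 17, a difference of 0.422 (0.572, 0.446 and 0.333 in the letter pairs). The size of the LPS change and the level of the genes were set against 10000 lists matched on both. The difference stood at their percentile 100 (middle 95% from -0.106 to 0.230), which argues against both only for genes drawn singly. Such lists lack the shared regulation of real ones, so their spread may be too narrow. The scaling was argued against by a difference of 0.458 with equal totals and 0.431 with TMM factors. NF-kB genes kept the highest share of the 18 lists with such genes. The lowest was 0.352 for heat shock genes (6 genes). Further medians were 0.459 for scavenger receptors (3 genes), 0.465 for cholesterol biosynthesis (3), 0.560 for MHC class I (6) and 0.573 for cytokines (18). A low median was thus not seen in the interferon list alone. Several of these lists are small, however, and only the gap between NF-kB and interferon genes was tested. A smaller rise of IFNB1, a member of the interferon list chosen after its values were seen, remains open, since it had 0 reads without LPS, 64.7 ± 35.6 normalized counts in LPS and 6.35 ± 4.28 in DCVC_LPS, so that both rises are lower bounds (at least 145-fold and at least 14.7-fold) and the log2 interaction of -3.21 depends on the pseudocount.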

How the results depend on the processing

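The alternatives that rescale to equal totals, average the letter pairs, leave LPS library A out of edgeR or exchange the parts of the LPS libraries were chosen only after seeing the data. Under the alternatives fixed beforehand every count of genes in the 5 comparisons stayed within 1.5 times its value, leaving out letters or single libraries included. The slope ran from 0.607 to 0.673 over other pseudocounts, minima, scalings, fits and letters left out, was 0.704 over genes with a mean of at least 1000, and ran from 0.603 to 0.686 in the letter pairs. With the letter as a replicate block the counts up and down were 5551 and 5966 for LPS, 4358 and 5105 for DCVC, and 5015 and 5944 for DCVC_LPS minus LPS. They were 4666 and 5078 for DCVC_LPS minus DCVC and 3917 and 3924 for the interaction. The slope with it was 0.647, and 51 of 140 list tests passed in place of 45. The block gave a call to the cholesterol list for LPS (adjusted p = 0.0453), DCVC (0.00959) and the interaction (0.00115). It did so for the cell cycle list for LPS (0.0375), DCVC (0.00959) and DCVC_LPS minus DCVC (0.0119) and for the progenitor markers with DCVC (0.0215). With letter pairs averaged none of these 7 list calls was made (0.0665 to 0.262). That fit has no term for the pairs, whose differences stay in its spread, while the block takes the letters as independent. Neither decides these calls. The block ended the call of the NRF2 list for the interaction (0.0507) and brought KYAT3 (DCVC_LPS minus DCVC, 0.0133) and NQO1 (interaction, 0.0161) past the threshold. It changed no other call of a list or named gene.

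Rescaled to equal totals, LPS raised 3119 genes, DCVC raised 6414 and lowered 2791, and 7578 were higher and 3051 lower in DCVC_LPS than in LPS. From DCVC to DCVC_LPS 2263 rose and 7322 fell, 4601 genes had a positive interaction, and 1667 and 5902 genes were in the raised-then-lower and lowered-then-higher overlaps, since rescaling moves the log2 changes of all genes by about the same amount. Between 97.25% and 99.25% of the calls of at least 2-fold kept their direction and call. With letter pairs averaged, 1679 and 2085 genes had a positive and a negative interaction, with 3 values per group and no term for the pairs. Of the list tests, 3 passed with an estimated correlation (cytokines for LPS and for DCVC_LPS minus DCVC, NRF2 targets for DCVC) and 97 with fry, which does not compare a list with other genes. Equal totals ended the calls of heat shock genes for LPS (adjusted p = 0.0839), cholesterol genes for DCVC_LPS minus LPS (0.101), MHC class I genes for DCVC_LPS minus DCVC (0.0902) and mitochondrial transcripts for the interaction (0.0571). They gave calls to the inflammasome list for LPS (0.0426), the NF-kB (0.0343) and cell cycle (0.0303) lists for DCVC and immediate early genes (0.0152) and scavenger receptors (0.0124) for DCVC_LPS minus LPS. For the interaction they did so for immediate early genes (0.0344) and lysosome genes (0.0344), as TMM factors did for the former (0.0425). With letter pairs averaged the calls of lysosome genes for DCVC (0.0502) and NRF2 targets for the interaction (0.052) were lost.

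Of 799 values of single genes, 732 kept direction and call under equal totals, 727 with letter pairs averaged, 779 in edgeR, 792 in DESeq2 and 779 with TMM factors. As libraries were left out, 15757 of 16074 did so. Log2 signs turned in edgeR for CCL3 (DCVC, -0.13), NQO1 (DCVC_LPS minus DCVC, -0.03), IL1B (interaction, -0.05) and CXCL10 (interaction, 0.35). Without LPS library A they turned for CCL3 (-0.13), NQO1 (-0.03) and CXCL10 (0.32). They turned in DESeq2 for CCL3 (-0.16) and IL10 (DCVC_LPS minus DCVC, 0.05), and with a pseudocount of 5 for IL10 (0.01). Under equal totals they turned for UQCRFS1 (-0.06), MCM7 (-0.05) and AZU1 (-0.14) with LPS and for PTGS2 (0.12), DNAJB1 (0.02), MT-ND6 (0.00) and ATP5F1B (0.03) with DCVC. In DCVC_LPS minus LPS they turned for ATP5F1B (0.03), CLEC11A (0.20), SRGN (0.16) and HLA-G (0.03), and for DCVC_LPS minus DCVC in NQO1 (-0.27), KYAT3 (-0.07), CTSS (-0.03) and COX7A2 (-0.06). Of these only CLEC11A passed the test with its sign turned. Leaving out libraries gave ranges that reach or cross 0 for IL6 (-0.27 to 0.00), CCL3 (-0.19 to 0.40), PTGS2 (-0.26 to 0.12) and NFKBIA (-0.09 to 0.25) with DCVC, IL10 (-0.47 to 0.14) for DCVC_LPS minus DCVC and IL1B (-0.23 to 0.30) for the interaction. None of these passed the test with all libraries. The cause was not tested for turns other than those of equal totals. Depth limits genes with few reads, such as IL6 and IL10 without LPS, where changes were not detectable at this depth.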

Other observations

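The grouping by letter pairs was noticed in the data and the overlap of CD68 was looked up after its value was seen, while the tests of the letter pairs and of the splits of single libraries were written down before their results were seen. The test of the share of reads in the leading genes and the splits with the letter pairs as units were chosen only after the result was seen. Lysosome genes rose more often than they fell with DCVC, but the call for DCVC alone was lost with letter pairs averaged. Of the lysosome and cathepsin genes, 13 of 25 rose and 5 fell (15 and 6 adjusted over the list alone, median log2 change 0.25, camera adjusted p = 0.0323, adjusted p = 0.394 with an estimated correlation, equal totals 16 and 3 at a median of 0.50) with DCVC alone. In DCVC_LPS against LPS 12 of 25 rose and 5 fell (12 and 5 adjusted over the list alone, median log2 change 0.16, camera adjusted p = 0.0157, adjusted p = 0.328 with an estimated correlation, equal totals 20 and 2 at a median of 0.59). GLA, the lysosomal alpha-galactosidase, rose with DCVC alone in 6 of 6 libraries (log2 change 1.49 ± 0.07, adjusted p = 3.65e-14), while the cathepsin CTSH had a log2 change of -1.97 ± 0.14. Of the heat shock genes, 12 of 17 rose and 2 fell (12 and 2 adjusted over the list alone, median log2 change 0.48, camera adjusted p = 0.0343, adjusted p = 0.636 with an estimated correlation, equal totals 8 and 6 at a median of 0.01) with LPS, a call that did not hold after rescaling to equal totals (adjusted p = 0.0839, 2.1e-08 to 0.636 over the alternatives). The chaperone HSP90AB1 had a log2 change of 1.37 ± 0.09. The interaction of heat shock genes was negative in 10 of 17 and positive in 1 (10 and 1 adjusted over the list alone, median log2 interaction -0.51, camera adjusted p = 0.027, adjusted p = 0.702 with an estimated correlation, equal totals 9 and 1 at a median of -0.33). Mitochondrially encoded transcripts were lower in DCVC_LPS than in LPS, where 0 of 13 rose and 13 fell (0 and 13 adjusted over the list alone, median log2 change -0.60, camera adjusted p = 0.00676, adjusted p = 0.543 with an estimated correlation), with MT-ND2, a complex I subunit, at -0.87 ± 0.12. Under equal totals the median was -0.17 and 2 fell, and the mitochondrial share of reads was 1.92% in both groups, so most of this fall comes with the deposited scale. Of the ATF4 stress genes in DCVC_LPS against LPS, 4 of 29 rose and 20 fell (4 and 20 adjusted over the list alone, median log2 change -0.60, camera adjusted p = 0.0257, adjusted p = 0.328 with an estimated correlation, equal totals 9 and 14 at a median of -0.17), with WARS1, a tRNA synthetase that interferon also induces, at -2.50 ± 0.11. Of the macrophage markers, 7 of 20 rose and 8 fell (7 and 8 adjusted over the list alone, median log2 change 0.04, camera adjusted p = 0.836, equal totals 11 and 5 at a median of 0.47) in the same comparison, with the costimulatory receptor CD40 at -1.99 ± 0.16.

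The interaction was negative in 12 of 17 MHC class I genes and positive in 0 (12 and 0 adjusted over the list alone, median log2 interaction -0.46, camera adjusted p = 0.000464, adjusted p = 0.507 with an estimated correlation, equal totals 9 and 1 at a median of -0.28). It was negative in 8 of 15 feedback regulators and positive in 1 (9 and 1 adjusted over the list alone, median log2 interaction -0.85, camera adjusted p = 0.00342, adjusted p = 0.409 with an estimated correlation), and in 5 of 13 mitochondrially encoded transcripts and positive in 0 (8 and 0 adjusted over the list alone, median log2 interaction -0.36, camera adjusted p = 0.0306, adjusted p = 0.778 with an estimated correlation, equal totals 1 and 0 at a median of -0.18). The mitochondrial call did not hold after rescaling to equal totals (adjusted p = 0.0571, 0.00821 to 0.778 over the alternatives). Of 23 cholesterol biosynthesis genes, 4 rose and 13 fell with LPS (4 and 13 adjusted over the list alone, camera adjusted p = 0.291), and 7 rose and 1 fell with DCVC (4 and 1 adjusted over the list alone, camera adjusted p = 0.165, equal totals 12 and 1 at a median of 0.55). With the replicate letter as a block both were called (adjusted p = 0.0453 and 0.00959, ranges over the alternatives 0.0453 to 0.867 and 0.00959 to 0.954). Neither was called with letter pairs averaged (0.262 and 0.173), in a fit without a term for the pairs.

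The lists that follow did not pass camera for LPS, DCVC or DCVC_LPS against LPS. Counts that rose and fell in these comparisons, in that order, were 4 and 1, 4 and 2, 3 and 3 of 9 for MHC class II genes, 8 and 4, 5 and 6, 4 and 6 of 20 for the unfolded protein response, 10 and 7, 4 and 7, 6 and 10 of 20 for p53 targets and 4 and 5, 4 and 4, 4 and 8 of 15 for LXR targets. They were 13 and 9, 5 and 12, 7 and 15 of 28 for glycolysis and hypoxia genes, 6 and 10, 5 and 10, 10 and 7 of 28 for the nuclear respiratory chain and 3 and 1, 0 and 2, 1 and 4 of 6 for metallothioneins. For the remaining lists they were 4 and 13, 0 and 9, 5 and 11 of 25 for cell cycle genes, 8 and 14, 11 and 11, 10 and 9 of 27 for cysteine conjugate and glutathione handling, 3 and 1, 7 and 2, 5 and 3 of 9 for myeloid progenitor markers and 2 and 2, 2 and 2, 3 and 3 of 6 for markers of other cell types. Under equal totals the same counts were 3 and 4, 6 and 2, 5 and 2 for MHC class II genes, 4 and 11, 10 and 1, 14 and 3 for the unfolded protein response, 8 and 10, 8 and 5, 9 and 8 for p53 targets and 3 and 9, 6 and 2, 4 and 3 for LXR targets. They became 6 and 15, 10 and 11, 11 and 12 for glycolysis and hypoxia genes, 2 and 23, 15 and 1, 23 and 1 for the nuclear respiratory chain, 2 and 1, 0 and 2, 1 and 4 for metallothioneins and 2 and 16, 1 and 6, 6 and 5 for cell cycle genes, and 4 and 20, 12 and 8, 17 and 6 for cysteine conjugate and glutathione handling, 2 and 2, 7 and 2, 7 and 1 for myeloid progenitor markers and 1 and 2, 3 and 1, 3 and 1 for markers of other cell types. The direction of most calls thus turned with the scale for the unfolded protein response and p53 targets in each of these comparisons. It also turned for MHC class II and glycolysis genes with LPS and for the nuclear respiratory chain with DCVC. In DCVC_LPS against LPS it turned for LXR targets and cell cycle genes. Adjusted over the list alone, the counts on the deposited scale differed in a few cases. In LPS minus Control they were 3 and 1 for MHC class II genes and 2 and 0 for myeloid progenitor markers. They were 4 and 9 for the nuclear respiratory chain in DCVC minus Control and 5 and 10 for cell cycle genes in DCVC_LPS minus LPS. The other counts were the same. With the replicate letter as a block the cell cycle list was called for LPS (adjusted p = 0.0375, 0.00257 to 0.804 over the alternatives) and DCVC (0.00959, 0.00959 to 0.954), as were the progenitor markers for DCVC (0.0215, 0.00021 to 0.697). These 3 calls were lost with letter pairs averaged (0.147, 0.104 and 0.0665), in a fit without a term for the pairs. Median, mean and test did not all share a sign in 16 of 140 list tests, none of which passed camera. The median was negative with a positive mean and an upward test for the ATF4 list with LPS (median -0.05, mean 0.27) and in DCVC_LPS against DCVC (median -0.02, mean 0.24) and for the inflammasome list in the latter (median -0.16, mean 0.74). The others were the macrophage list with LPS and in DCVC_LPS against LPS, the immediate early list with DCVC, the unfolded protein response with DCVC, in DCVC_LPS against LPS and for the interaction, and MHC class II in DCVC_LPS against LPS. They also were LXR targets in DCVC_LPS against DCVC and for the interaction, the cholesterol list and markers of other cell types in DCVC_LPS against DCVC, and the ATF4 and glycolysis lists for the interaction.

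CD68, a macrophage marker that was looked up after its value was seen, had a mean of 14.4 normalized counts, and 81.73% of its exon bases overlap another gene on the same strand in GENCODE 29, so that the handling of shared reads, not given in the sources used here, enters its count.

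Libraries grouped by the letter pairs A/B, C/D and E/F in every group, with 36 of 36 matches between groups in the same pair both with all genes and without the leading 10 and the mitochondrially encoded ones, a count at its limit that decides nothing. Sequencing depth was argued against, since 11 of 15 ways to pair the letters had a mean gap in log2 reads as small as the real one. A few genes taking most of the counts were argued against, since these genes held at most 12.74% of reads in any library, and their share allows a shift of the other genes by 0.03 log2 between letter pairs, against a median range of 0.35 for the genes that differ. A shared culture, plate or day may be the cause, with 7615 genes (54.78% of those tested) that differed between the letter pairs at fixed group, but it cannot be told apart from other sources because the labels do not say what the letters mark. Of 25 cell cycle genes 24 differed between the pairs, as did 22 of 23 cholesterol biosynthesis genes, 13 of 13 mitochondrially encoded transcripts and 18 of 20 genes of the unfolded protein response.

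With single libraries as units, chance was argued against for the counts of genes in all 5 comparisons, since in each only 1 of 100 drawn splits of the libraries, the real one, gave as many calls. The real and the highest other counts were 10892 and 8496 for LPS minus Control, 8298 and 5274 for DCVC minus Control, 10111 and 7219 for DCVC_LPS minus LPS, 8635 and 5531 for DCVC_LPS minus DCVC, and 6350 and 1322 for the interaction, where residuals of the additive model were regrouped. Among the 32 splits that part all 6 letters, again 1 gave as many, and the highest other counts were 8307, 4526, 7415 and 5117. Splits that mix the groups unevenly hold part of the real difference. Libraries of a letter pair are not independent, and with the means of the letter pairs as units 1 of 10 splits gave as many calls as the real one, namely itself, in the 4 comparisons of groups. The real counts were then 9668, 6177, 8634 and 6788 and the highest other count was 0 in each, and 10 splits are too few for a share under 0.05.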
